A study of Homo sapiens with 6 samples.

How the data were processed

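RNA sequencing was carried out by the authors on K562 cells, an established human leukaemia line that carries the BCR-ABL1 fusion kinase. The labels describe 6 libraries in 3 groups of 2. The groups are the imatinib-sensitive parent (WT) and the imatinib-resistant lines IR1 and IR2. Imatinib inhibits the ABL kinase. Per the labels' protocols, both resistant lines were kept under the drug throughout, and its concentration is not given in the sources used here. In each group the labels mark the other library as a repeat, and nothing says that the libraries came from separate cultures, so any spread between them may be technical.

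The single table used here holds Ensembl gene identifiers and log2 fold changes, in 2 columns that the authors deposited as the genes common to their comparisons of WT with IR1 and of WT with IR2. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts, Subread and DESeq2 3.5 were used with the human build hg19, and neither the role of each tool nor its settings are given in the sources used here. Each of the 674 genes has an absolute log2 fold change above 1.5 in both columns, which is a property of the values, not a stated filter. The adjusted p limit of the authors' selection, the strand setting of the counting and the treatment of reads that fit several genes are not given in the sources used here.

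The header of the deposited table says neither which log2 fold change column belongs to which resistant line nor which group is the numerator. The table's name puts the IR1 comparison ahead of the IR2 comparison, which does not fix the order of the columns. The columns are therefore called the first and the second, and genes are called positive or negative by the sign of the fold. The planned contrast of IR1 with IR2 is given as a contrast of the first with the second column. Standard errors, p-values, mean expression and values per library were not used here, so the depth behind each value is unknown, no fold has an error or a replicate number, and no difference for a single gene was tested. Planned steps that need such columns were not run. These are the count model per library, the test of the difference between lines per gene, the covariance of the fold changes, the overlap of independent call lists and the split of the control libraries.

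Symbols came from a gene name table that matched 654 of the 674 identifiers. Gene type, chromosome and gene order came from GENCODE release 29 on the build GRCh38, which held 657 of the identifiers and lacked 17. That build differs from the authors' hg19, so it served for gene type, overlap of gene bodies and neighbourhood alone and no coordinates are printed. Symbols other than clone or accession names were found for 593 genes. The number of identifiers or symbols listed more than once was 0.

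Genes were counted by sign. Both comparisons use the same WT libraries, so the same-sign share was set beside a simulation of unchanged lines, with pairs of z values correlated at 0.5 and kept where both passed a two-sided p of 0.05, until 100000 pairs were kept. Pearson's r and Spearman's rho across genes are descriptions without a p-value, since genes are not independent replicates. The size of the folds was compared through the median over genes of the absolute log2 fold change in the second column minus that in the first, with a 95% bootstrap interval over genes from 10000 draws. Protein-coding genes were compared with long non-coding RNAs and pseudogenes by a two-sided permutation test on this difference with 100000 permutations.

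There were 28 gene lists, covering cell types, signalling, stress, adhesion, antigen and gene family groups. For lists with 5 or more listed members, the sign of the members was compared with that of the other listed genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 10 lists tested and a threshold of 0.05. The same test was applied to gene types and, over all chromosomes with listed genes except Y, to chromosomes. The set of genes that the authors tested is not in hand, so enrichment of a list among expressed genes was not tested. Adjacent listed genes within 1 Mb on a chromosome were compared for sign with 10000 permutations of the signs over genes, one-sided, which can give no p below 0.0001. Genes are not independent, and these tests describe the table alone.

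Genes named in the text were taken by a rule. It takes the 12 genes with the highest and the 12 with the lowest mean of both log2 fold changes, up to 5 genes per sign with the largest difference of absolute log2 fold change between columns, and up to 4 members per list by absolute mean. All members of the erythroid, drug transport and BCR-ABL1 component lists come under the rule, and genes without a proper symbol are left out. Values of some list members are not reported here, though these genes stay in every count and test. The rule gave 94 genes with reported values. A further 52 genes were chosen after their values were seen, and the text says so. The lists, the rule, the tests of sign, size and neighbourhood and most alternatives were fixed before the data were examined. The chromosome and gene type tests, the comparison of coding with non-coding genes, the test of fold similarity between neighbours, and the alternatives that use gene type, overlap, zinc finger genes as a family or chromosome 19 were chosen afterwards.

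Alternatives tried were a minimum absolute log2 fold change of 1 or 2, a single entry per symbol, protein-coding genes alone, the ratio of linear folds, signs from a single column, windows of 200 kb and 5 Mb, and the omission of overlapping or related neighbours. Neighbours counted as a family where their symbols shared the first 3 letters, alone or with pairs of zinc finger list members added. The computations used Python 3.11.15, numpy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. The procedures were tested on simulated data, 100 data sets over the 657 placed genes each. With shuffled signs the neighbour test called 3% of data sets, and with 40% of pairs copied it called 100%. The test of fold similarity between neighbours called 4% of data sets with permuted folds and 100% with 50% of pairs copied. Random lists of 12 genes were called in 0.125% of cases, and lists of 12 drawn mostly from negative genes in 100%. Shorter lists and lists drawn mostly from positive genes were not simulated, so the 100% does not extend to them.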

Results

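Gene expression in the K562 chronic myeloid leukaemia line was compared between the imatinib-sensitive parent (WT) and the imatinib-resistant lines IR1 and IR2, to find the genes that differ from the parent in both. RNA was sequenced from 6 libraries, 2 per group. The resistant lines were kept in imatinib, so resistance and drug exposure are not separated by this design. The values are the authors' log2 fold changes for the 674 genes shared by their comparisons, without errors, p-values or depth, so no fold could be set against the spread between libraries. The header does not say which column belongs to which line, nor whether a positive fold means higher in the resistant lines or in WT.

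LIN28A (ENSG00000131914), an RNA-binding protein best known from pluripotent stem cells, had the highest mean fold among genes with a proper symbol, with log2 fold changes of 5.61 in the first and 6.97 in the second column of the authors' deposited table. For ZFP42, a zinc finger protein that marks pluripotent cells, the authors' deposited table gave 4.95 and 5.50, and for B3GAT1, the enzyme that makes the CD57 carbohydrate epitope, 5.28 and 5.72. At the other end, THRB (ENSG00000151090), the thyroid hormone receptor beta, stood at -5.83 and -6.28 in the authors' deposited table. SCG3, a secretory granule protein, followed with -5.50 and -5.85 in the authors' deposited table, and CCND2 (ENSG00000118971), the G1 phase cyclin D2, with -3.89 and -6.91.

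Among the shared genes, 501 (74.3%) were positive in both columns, 173 (25.7%) were negative in both and 0 had opposite signs. The other protein-coding genes among the 12 highest were KLHL6 (5.74 and 4.28), MAEL (5.88 and 4.10), which acts in the piRNA pathway of the germ line, and the histone variant gene MACROH2A2 (5.25 and 4.69), all as log2 fold changes of the authors' deposited table. The rest of the 12 were the long non-coding RNAs LINC01091, LINC02434, LINC01257 and LINC02575, the antisense RNA TRPM2-AS and the pseudogene LETM1P2, with log2 fold changes in the authors' deposited table from 4.21 to 6.94. Among the 12 lowest, GYG2, a glycogenin that primes glycogen synthesis, had log2 fold changes of -4.14 and -6.22 in the authors' deposited table. In the same group of 12, the authors' deposited table gave -4.88 and -5.11 for the carboxypeptidase gene CPZ, -4.23 and -4.88 for TMOD2, a tropomodulin that caps actin filaments, and -4.13 and -4.22 for FUT8, the core fucosyltransferase. HS3ST3A1, a heparan sulfate sulfotransferase, stood at -3.50 and -4.82 in the authors' deposited table. EGFLAM-AS4, PHF2P2, THRB-IT1 and USP24P1 completed the 12 lowest, with log2 fold changes between -3.42 and -5.72 in the authors' deposited table. THRB-IT1 lies within THRB, and PHF2P2, USP24P1 and LETM1P2 are copies of other genes, so their values are uncertain where reads fit both.

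The median log2 fold change of the positive genes in the authors' deposited table was 2.28 in the first column (quartiles 1.81 and 2.94, a 4.86-fold median) and 2.92 in the second (quartiles 2.28 and 3.89, 7.57-fold). For the negative genes of the authors' deposited table it was -2.23 (quartiles -2.93 and -1.78, 4.71-fold) and -2.77 (quartiles -3.65 and -2.12, 6.82-fold). A fold of 16 or more was reached by 37 positive genes in the first column and 113 in the second, and by 14 and 35 negative genes, in the authors' deposited table. Comparisons with the same WT libraries share their chance values. In simulated unchanged lines 99.9% of the genes passing in both comparisons had the same sign, against 100% observed.

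**Figure D1:**
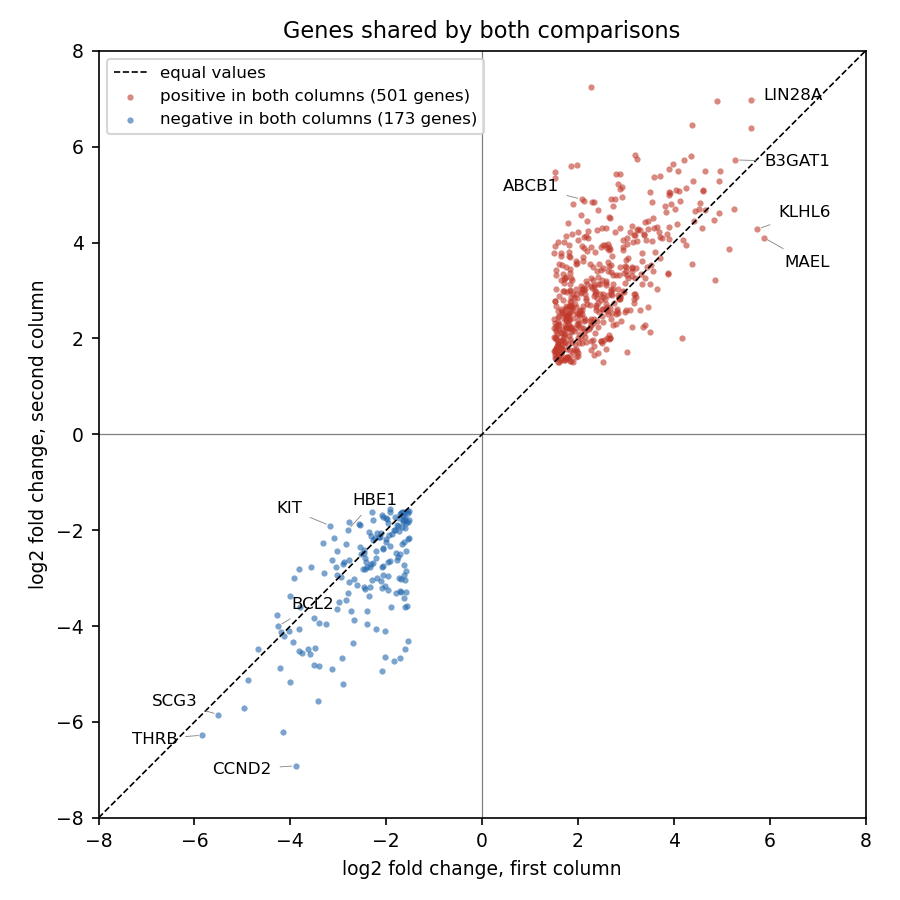
Log2 fold change in the first column (x axis) against the second column (y axis) of the authors' deposited table, 1 point per gene, with the line of equal values dashed. All 501 positive and 173 negative genes lie in the quadrants of shared sign, no value lies within 1.5 of 0, and ABCB1 and CCND2 lie far from the dashed line.

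Protein-coding genes made up 480 of the 674 entries (71.2%), long non-coding RNAs 107 (15.9%) and pseudogenes 69 (10.2%). Positive folds were held by 352 of the protein-coding genes, 84 of the long non-coding RNAs and 51 of the pseudogenes. None of these types, nor the 17 identifiers outside the annotation, differed in sign from the other listed genes in Fisher's exact test (adjusted p from 0.763 to 1). The remaining gene was TRBC2, a T cell receptor constant segment.

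ABCB1 (ENSG00000085563), the drug efflux pump P-glycoprotein, had a log2 fold change of 2.08 (4.22-fold) in the first and 4.90 (29.9-fold) in the second column of the authors' deposited table. CCND2 differed in the same way among negative genes, with folds of 14.8 and 121 in size in the authors' deposited table. Other protein-coding genes with a wide gap were NMU, the neuropeptide neuromedin U (-1.71 and -4.66), and APOL4, an apolipoprotein L gene (-1.54 and -4.30), in the authors' deposited table. The non-coding RNAs PDE7B-AS1 (1.86 and 5.60), LINC01404 (3.20 and 5.83), ADIRF-AS1 (1.79 and 4.40) and MGC12916 (-2.08 and -4.94) also had wide gaps in the authors' deposited table. Of the copies of other genes, HNRNPDLP4 (2.87 and 5.42) and CD24P4 (-1.83 and -4.73) also had wide gaps in the authors' deposited table. CD24P4 is annotated on chromosome Y and shares sequence with CD24 itself. Its values may come from reads of CD24 and cannot be taken as a change of the pseudogene.

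Across genes the absolute log2 fold change was larger in the second column for 517 of the 674 genes (76.7%) and larger in the first for 157. The median difference in the authors' deposited table was 0.47 (95% bootstrap interval over genes 0.39 to 0.55), a 1.39-fold ratio of the folds. For positive genes the median difference in the authors' deposited table was 0.53 (0.44 to 0.60), with 393 genes larger in the second column and 108 in the first. For negative genes of the authors' deposited table it was 0.34 (0.24 to 0.53), with 124 and 49 genes. A gap of over 2-fold in favour of the second column was seen for 128 positive and 40 negative genes, and in favour of the first for 10 and 3. Among protein-coding genes the median difference in the authors' deposited table was 0.31 (0.25 to 0.38), against 0.94 for the 176 long non-coding RNAs and pseudogenes together. This contrast of 0.63 had a permutation p of 1e-05, the smallest that the permutations can give, and the median over all genes was over 1.5 times that of protein-coding genes. Pearson's r between the columns was 0.948 over all genes (Spearman's rho 0.826), where z values of simulated unchanged lines gave 0.975. Within the positive genes r was 0.631 (rho 0.596) against 0.141 for simulated z values, and within the negative genes 0.654 (rho 0.547). Folds and z values are unlike quantities, so the excess over the simulated value is no measure of a shared effect. The WT libraries could not be split, and part of the excess may come from their sharing. The correlations are across genes, which are not independent replicates.

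Erythroid genes carried mostly negative folds: 6 of the 7 listed members of the erythroid list were negative. The embryonic globin gene HBE1 (-2.80 and -2.00) and the alpha globin gene HBA2 (-2.57 and -1.88) had the largest negative folds of the list by mean in the authors' deposited table. The glycophorin gene GYPB (-2.00 and -1.74), the Rh-associated glycoprotein gene RHAG (-1.65 and -1.82) and GYPE (-1.52 and -1.60) were also negative in the authors' deposited table. The exception was TRIM10, a RING finger gene of erythroid cells, at 1.84 and 3.36 in the authors' deposited table. The list was negative more often than the other listed genes (Fisher's exact p = 0.00147, adjusted p = 0.00737). GYPB and GYPE, like HBA2 and HBA1, are close copies whose reads may be split or shared.

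Output genes of ERK and STAT5 signalling, which act downstream of BCR-ABL1, were negative for 5 of 6 listed members. Beside CCND2, these were the feedback inhibitors SOCS1 (-2.44 and -3.22) and CISH (-1.59 and -2.85) and the kinase PIM1 (-1.78 and -2.63) in the authors' deposited table. ID2, chosen after its value was seen, stood at -2.31 and -1.62 in the authors' deposited table. CCND1 (cyclin D1), also chosen afterwards, was the positive member, at 2.08 and 1.90 in the authors' deposited table. The list differed in sign from the other listed genes (Fisher's exact p = 0.00506, adjusted p = 0.0169). It pools targets of both pathways, and no DUSP, SPRY, SPRED, ETV or EGR gene of the list was among the 6 listed members. The signs therefore do not show that ERK output moved with STAT5 output. With a minimum absolute log2 fold change of 2, this list and the erythroid list had fewer than 5 members left and could not be tested.

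Zinc finger genes, taken by symbols that start with ZNF, ZFP, ZSCAN or ZKSCAN, formed the list with the most listed members, with 52 of 54 listed members positive. ZFP42 was joined by ZSCAN1 (4.08 and 5.49), ZNF875 (4.25 and 5.14) and ZNF732 (3.90 and 5.0) in the authors' deposited table. The negative members, chosen after their values were seen, were ZFPM2, a cofactor of GATA factors (-3.08 and -2.17), and ZNF608 (-1.64 and -1.63) in the authors' deposited table. The list was positive more often than the other listed genes (Fisher's exact p = 1.58e-05, adjusted p = 0.000158). All 38 members on chromosome 19 were positive. Of the 16 members elsewhere 14 were positive, which did not pass the threshold against the other listed genes (Fisher's exact p = 0.258, adjusted p = 0.503). Zinc finger genes made up 13.9% of positive protein-coding genes (49 of 352), 1.56% of negative ones (2 of 128) and 2.85% of all annotated protein-coding genes (568 of 19951). The last share covers annotated genes whether or not they are expressed in K562 cells, and it goes by GENCODE symbols. Listed genes went by the gene name table where it held them, so the shares are not fully alike and show no enrichment. Many zinc finger genes are close paralogs, and reads that fit several of them are a limit on single values.

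**Figure D2:**
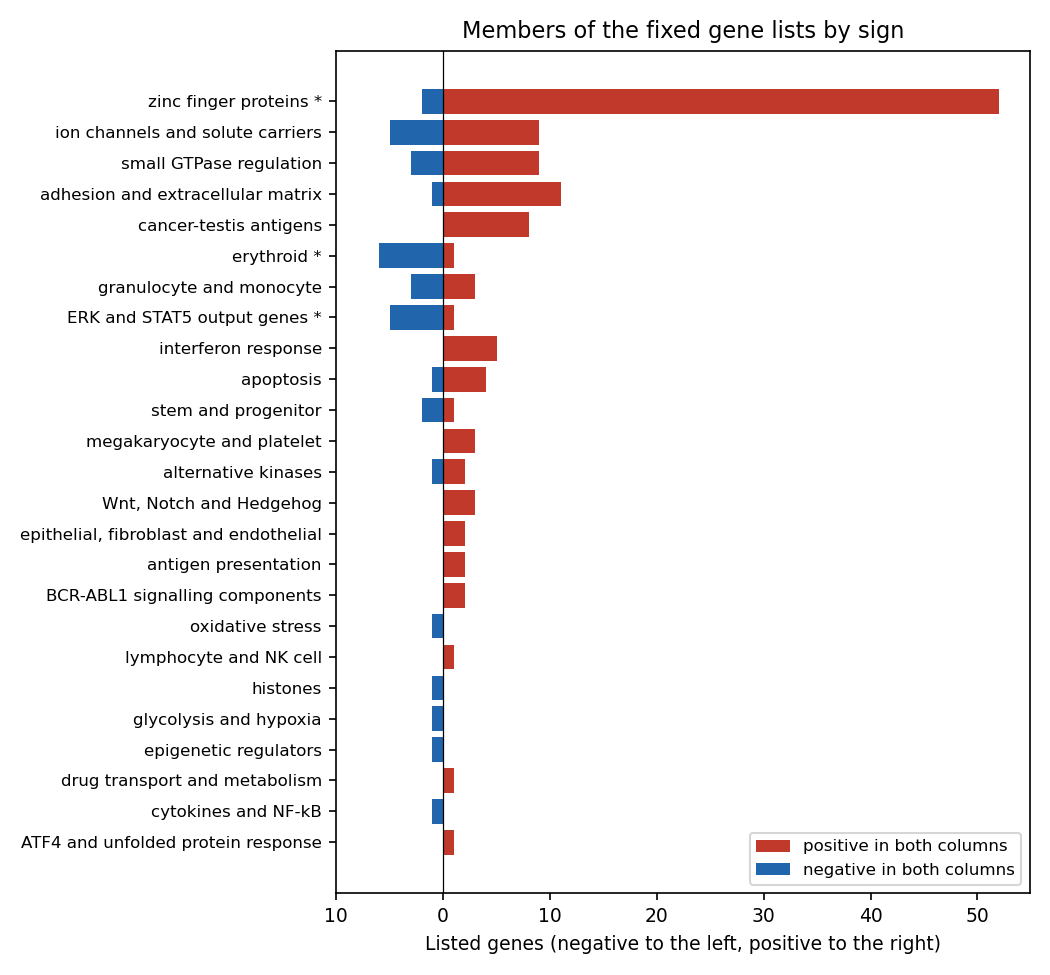
Number of listed genes per fixed gene list, positive genes to the right of 0 and negative genes to the left. An asterisk marks the 3 lists past an adjusted p of 0.05 in Fisher's exact test, and the 52 positive zinc finger genes form the longest bar.

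The other tested lists did not pass the threshold for a difference in sign from the rest of the table (Fisher's exact test). For short lists this says little about positive folds, because 74.3% of all listed genes were positive. Lists of 5 or 8 members could not pass in that direction, even with every member positive (Fisher's exact p = 0.336 and 0.122, unadjusted). Cancer-testis antigen genes, which are normally active in the germ line, were positive for 8 of 8 members (adjusted p = 0.304), led by MAGEA1 (3.64 and 4.32), SSX1 (3.69 and 4.23), SSX6P (2.41 and 4.68) and MAGEB17 (2.99 and 3.41) in the authors' deposited table. Interferon response genes were positive for 5 of 5 members (adjusted p = 0.458). These included the antiviral genes OAS3 (3.61 and 3.80) and IFITM3 (3.56 and 3.40), with GBP2 (2.64 and 3.84) and LGALS3BP (3.41 and 2.28), in the authors' deposited table. GBP4, chosen after its value was seen, was the last member, at 1.95 and 3.56 in the authors' deposited table. Adhesion and matrix genes were positive for 11 of 12 members (adjusted p = 0.458). The authors' deposited table gave 4.39 and 5.27 for the collagen gene COL1A1, 4.53 and 4.70 for the hyaluronan receptor CD44, 3.70 and 5.38 for COL26A1 and 2.94 and 3.85 for CDH4. The fibronectin gene FN1, chosen after its value was seen, was the negative member, at -2.34 and -3.18 in the authors' deposited table.

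Apoptosis genes were positive for 4 of 5 members (adjusted p = 1), while the survival gene BCL2 stood at -4.25 and -4.0 in the authors' deposited table. The positive members included CASP4 (2.83 and 2.90), the cell cycle inhibitor CDKN1A (1.86 and 3.27) and the death receptor FAS (2.37 and 2.66) in the authors' deposited table. Granulocyte and monocyte genes were split evenly, with 3 of 6 members positive (adjusted p = 0.359). TYROBP (3.5 and 2.13) and the cytokine receptor CSF2RB (1.69 and 2.99) were positive in the authors' deposited table, while FCGR2B (-1.97 and -2.96) and CEBPD (-1.93 and -2.64) were negative. CD33 (1.81 and 2.05) and ITGAM (-1.58 and -2.44), chosen after their values were seen, were the others in the authors' deposited table. FCGR2B has the near-identical copy FCGR2C, also named after the values were seen, and is uncertain for that reason.

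Ion channel and solute carrier genes were positive for 9 of 14 members (adjusted p = 0.458). The pseudogene SLC9A3P2 (3.99 and 5.63), the sodium channel gene SCN9A (-3.94 and -4.33), the cation channel gene TRPM2 (3.5 and 3.14) and SLC16A10 (3.22 and 2.87) had the largest folds of the authors' deposited table in this list. Its other negative members, chosen after their values were seen, were SLC26A11, SLC9A2, SLCO4C1 and SLC7A8. Small GTPase regulators were positive for 9 of 12 members (adjusted p = 1), led by ARHGAP10 (3.91 and 4.08), RAB27B (3.71 and 3.69), RAP1GAP2 (2.42 and 3.28) and DOCK2 (2.80 and 2.50) in the authors' deposited table. The negative members RAB6B, RAB11FIP5 and ARHGEF3 were chosen after their values were seen, as was RHOXF2B, a homeobox gene caught by its name, without which 8 of 11 were positive.

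Of the lists with fewer than 5 members, which were not tested, drug transport and metabolism held ABCB1 alone. The BCR-ABL1 component list held the adaptor gene DOK2 (3.33 and 3.13) and the phosphatase gene INPP5D (1.78 and 1.89), both positive in the authors' deposited table. Megakaryocyte genes were positive for 3 of 3 members, namely the platelet integrin ITGA2B (3.46 and 4.45), RAB27B and NRGN (2.13 and 3.0), in the authors' deposited table. Of the stem and progenitor genes CD44 was positive, and ALDH1A1 (-2.44 and -2.81) and the receptor KIT (-3.17 and -1.91) were negative in the authors' deposited table. KIT was also in the alternative kinase list, beside DDR2 (1.60 and 2.30) and MERTK (1.74 and 1.56) in the authors' deposited table. The class I antigen genes HLA-B (1.52 and 2.79) and HLA-C (1.64 and 2.12), which share sequence, were positive in the authors' deposited table. The Wnt, Notch and Hedgehog list held FZD3 (3.12 and 4.34), NOTCH2 (3.01 and 2.60) and HEY1 (2.71 and 2.53) with positive folds in the authors' deposited table. Markers of other cell types were few: TRBC2 (4.05 and 5.09) for lymphocytes and COL1A1 and ACTA2 (2.09 and 3.92) for fibroblasts in the authors' deposited table. Lists with a single member were cytokines with IL1R1 (-3.81 and -2.80), hypoxia with BNIP3 (-1.70 and -1.65), the unfolded protein response with ATF5 (3.17 and 2.74) and oxidative stress with AKR1C2 (-1.76 and -1.92) in the authors' deposited table. Histones were represented by HIST2H2AA3 (-2.84 and -3.46), which has an identical copy, and epigenetic regulators by PRDM9 (-2.46 and -3.18) in the authors' deposited table. The cholesterol and lipid, proliferation and HOX lists had 0 listed members.

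**Figure D3:**
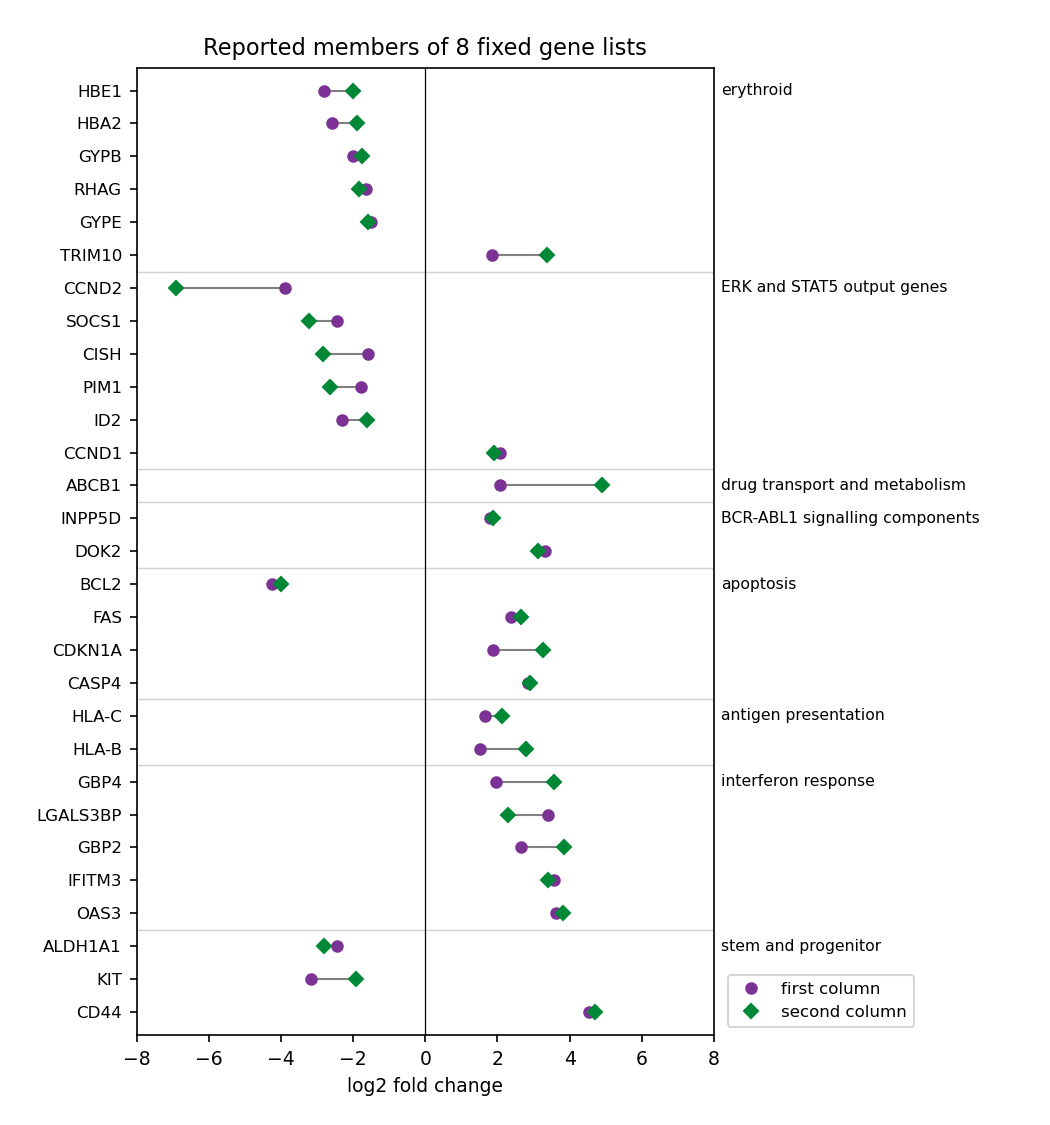
Log2 fold change of the reported members of 8 fixed gene lists, from the first column (circles) and the second column (diamonds) of the authors' deposited table, joined by a line per gene. Erythroid and ERK and STAT5 output genes lie mostly to the left of 0, interferon genes to the right, and ABCB1 and CCND2 have the longest lines.

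Chromosome 19 carried 75 listed genes, of which 73 (97.3%) were positive. The negative ones, chosen after their values were seen, were TLE2, a corepressor (-1.67 and -2.29), and the pseudogene LILRP1 (-1.80 and -2.48) in the authors' deposited table. Chromosome 3, the site of THRB, had 11 positive genes of 24 (45.8%). Both chromosomes differed in sign from the other listed genes (Fisher's exact test, adjusted p = 7.35e-07 for chromosome 19 and 0.0335 for chromosome 3), and the other chromosomes tested did not pass the threshold. The test takes genes as independent, though neighbours often shared their sign. On chromosome 3 it counted THRB, THRB-IT1 and THRB-AS1, a run of 3 negative neighbours at the THRB locus, as separate genes. The chromosome 3 result may rest on this locus, and no test without it was run. Without the members of the zinc finger list chromosome 19 still had 35 positive genes of 37 (Fisher's exact p = 0.000947). The list goes by symbol and leaves out antisense names. Zinc finger genes under other names, such as ZIK1, and the non-coding ZNF667-AS1 therefore remain among the 37. Listed genes that lie between zinc finger genes, such as LINC01535, remain too, so the 37 are not independent of the zinc finger loci.

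**Figure D4:**
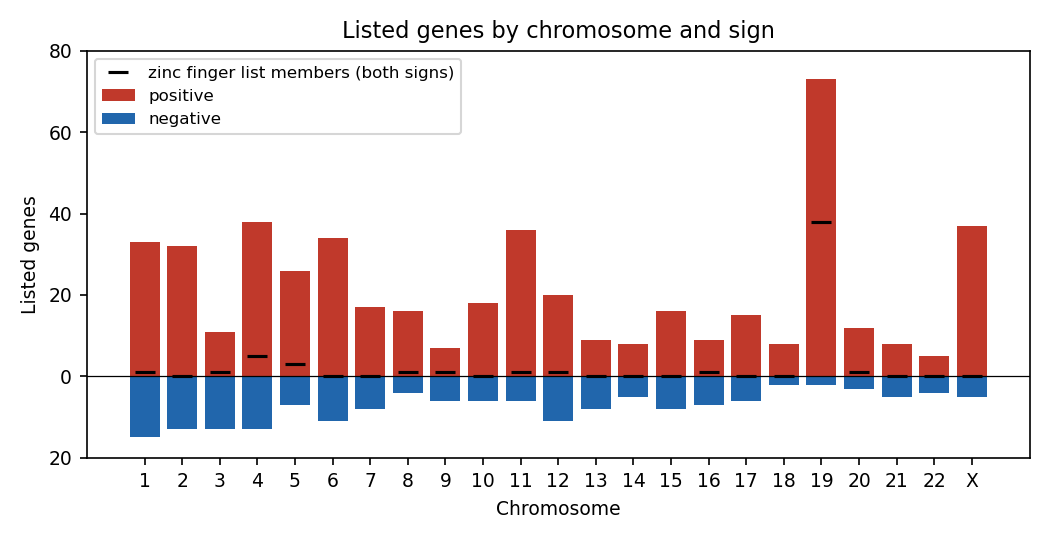
Number of listed genes per chromosome, positive above and negative below 0, with a black mark for the number of zinc finger list members. Chromosome 19 has 73 positive and 2 negative genes, and 38 of them are in the zinc finger list.

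Neighbouring genes often had the same sign. The runs given here, and the genes outside the naming rule in them, were chosen after the values were seen. The longest runs of positive neighbours were on chromosome 19, with 27 genes from SYT5 to ZNF329 (16 of them in the zinc finger list) and 12 genes from TYROBP to ZNF527 (7 in that list). A further run of 11 genes on chromosome 19, from CD37 to CD33, had 0 members of the zinc finger list. Negative runs were shorter, such as the 5 genes DMXL2, AC066613.1, SCG3, LYSMD2 and TMOD2 on chromosome 15. Of 270 pairs of adjacent listed genes within 1 Mb, 237 (87.8%) shared their sign, against 61.8% with permuted signs (central 95% of permutations 56.3 to 67.4%). The permutation p was 0.0001, the smallest that the permutations can give. Signs were permuted over all placed genes, and no permutation within chromosomes was run. The excess therefore includes differences between chromosomes, such as the high positive share of chromosome 19, and is no measure of similarity between neighbours alone. Overlapping gene bodies made up 41 of the pairs, all of the same sign, 33 of them on opposite strands. Since the strand setting is unknown, reads in such overlaps cannot be assigned to either partner.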

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

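Of 64 alternative values, 35 could not move and say nothing about stability: the minimum absolute log2 fold change of 1 and the single entry per symbol removed 0 genes, signs from a single column were the same in both, and the ratio of linear folds restates the median difference. A further 8, for neighbours, lay at the smallest p that permutations can give. Of the other 21, 13 kept their side of the threshold or stayed within their interval. The alternatives with protein-coding genes alone, without overlapping pairs, without families in which zinc finger genes count together, without both, and without the zinc finger genes of chromosome 19 were chosen after seeing the data. A minimum of 2 left 397 genes (296 positive). It moved Pearson's r between the columns from 0.948 to 0.961 over all genes and from 0.631 to 0.574 over positive genes, and left 1 list past the threshold in place of 3, since the erythroid and the ERK and STAT5 lists then had too few members for a test. The zinc finger list stayed past it, with an adjusted p of 0.00343. With the 480 protein-coding genes alone r was 0.961 over all and 0.697 over positive genes. The median of the second minus the first column in absolute log2 fold change of the authors' deposited table was then 0.31 over all (0.47 with every gene type) and 0.33 over positive genes (0.53 with every type); the wider gap of non-coding genes accounts for this by construction. Without the zinc finger genes of chromosome 19 the zinc finger list had an adjusted p of 0.503 in place of 0.000158; the omission left 16 members. The share of neighbours with the same sign, 87.8% of pairs within 1 Mb, was 78.8% within 5 Mb, 97.8% within 200 kb and 82.4% of 187 pairs without overlapping and family pairs together; the permuted mean for these 187 was 61.8% (95% of permutations 55.1% to 68.4%). No paired analysis was possible because the table holds no values per library. For the same reason the count models, the fit without a filter and the omission of single libraries were not run, nor were the limits on adjusted p and expression level and the covariance correction, which need columns outside the table. Depth and replicate error are unknown, so the reliability of single folds, above all of weakly expressed genes, cannot be ranked.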

Other observations

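The genes in this paragraph, apart from PRDM9, were chosen after their values were seen. No list of germ-line genes was fixed and no tally of them was made, so they stand as single genes and not as a group. Of genes known from the germ line outside the cancer-testis list, RNF17 (4.41 and 4.44), the synaptonemal complex gene SYCP2 (3.09 and 4.21), TDRD6 (2.52 and 1.5) and TEX19 (2.49 and 1.94) were positive in the authors' deposited table. The piRNA-binding gene PIWIL4 (1.79 and 2.30), DDX53 (2.11 and 3.05) and NLRP14 (1.75 and 2.38) were positive too in the authors' deposited table. Others were negative in the authors' deposited table, such as the meiotic gene PRDM9 (-2.46 and -3.18) and the spermatogenesis-associated gene SPATA12 (-1.52 and -1.80). Of the cancer-testis list itself, PAGE1 (2.69 and 3.54), PAGE4 (1.99 and 2.30), MAGEB16 (3.17 and 2.82) and MAGEB1 (2.69 and 2.41) completed the members in the authors' deposited table.

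Further single genes, also chosen after their values were seen, follow as values. WAS (2.59 and 2.61), LCP2 (2.53 and 2.61), CORO1A (2.13 and 2.36) and the NADPH oxidase subunit NCF4 (1.85 and 2.67) were positive in the authors' deposited table, whereas the inflammasome adaptor PYCARD (-1.71 and -2.50) was negative. The guanylate-binding protein GBP5, next to GBP2 and GBP4 on chromosome 1, stood at 3.89 and 5.06 in the authors' deposited table. Beside HS3ST3A1 on chromosome 17 lay its paralog HS3ST3B1 (-2.03 and -4.64), and beside APOL4 on chromosome 22 its paralog APOL1 (-2.09 and -3.21), both negative in the authors' deposited table. On chromosome 3 THRB-AS1 (-3.41 and -4.84) accompanied THRB and THRB-IT1 in the authors' deposited table. On chromosome 21 TSPEAR (2.14 and 3.03) and its antisense genes TSPEAR-AS1 (1.88 and 4.18) and TSPEAR-AS2 (3.55 and 4.02) shared the sign of TRPM2 and TRPM2-AS in the authors' deposited table. GLB1L3 (2.81 and 2.57) and B3GAT1-DT (3.56 and 4.50) flanked B3GAT1 on chromosome 11 in the authors' deposited table.

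Of the tests that follow, those without overlapping pairs, without families (zinc finger genes counted as a family), of fold similarity between neighbours, of a single scaling factor, of protein-coding genes alone and of the sign of the folds were chosen after the data were seen. Neighbouring listed genes shared their sign more often than permuted genes. The permutations crossed chromosomes, so differences between chromosomes in the share of positive genes add to this excess in each test of sign below. Overlapping gene bodies that share reads are not the whole source. Without overlap, 85.6% of the 229 pairs shared their sign (permutation p = 1e-04, the smallest that permutations can give). Of the 213 pairs outside a family by the naming rule, 84.5% did so too (permutation p = 1e-04). Families as drawn by that rule are not the whole source either. Relatives with unlike names stay in and unrelated genes with like names drop out, so clustered families were not fully removed. Copy number blocks would give neighbours similar folds: without overlap the median gap between neighbours was 0.67 against 0.78 with permuted folds of the authors' deposited table (p = 0.0495), but 0.73 against 0.78 without families as well (p = 0.267). Copy number therefore cannot be told apart from regional regulation, as no DNA measurement was used here. Regional regulation in the resistant lines or a change of chromosome content in them remain hypotheses, and neither was tested directly.

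The second column held larger folds than the first. A single scaling factor on the expression values would add the same amount to every log2 fold of a column, whatever its sign. The median of the second minus the first was 0.53 for positive and -0.34 for negative genes of the authors' deposited table. Such an added amount is therefore not the whole source. A factor that multiplies the log2 folds would enlarge both signs, and these medians cannot exclude it. Non-coding genes, which are often counted from few reads, are not the whole source either, because protein-coding genes alone had a median difference in absolute log2 fold change of 0.31 (0.25 to 0.38) in the authors' deposited table. Shrinkage or the spread between libraries could differ between the authors' comparisons and was not tested. A resistant line that lies farther from WT is a candidate explanation that stays open, and the line cannot be named because the header does not give it.

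The orientation of the folds stays open. ERK and STAT5 output genes were negative for 5 of 6 listed members (Fisher's exact p = 0.00506), a value seen before it was set against the orientation, so it decides nothing. The same signs would follow if positive means higher in the resistant lines and imatinib still holds BCR-ABL1 output down, or if positive means higher in WT and that output is raised in the resistant lines. No level per group was used here to decide.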
